A study of Mus musculus with 8 samples.

How the data were processed

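Polyadenylated RNA was sequenced from mouse embryos at the late morula stage, 78 h after fertilization, which the sample titles give as embryonic day 3.25. Zygotes had been injected with small interfering RNA (siRNA) against Rbbp4, against Rbbp7, against both, or with a non-specific siRNA, per the labels' treatment fields. Rbbp4 and Rbbp7 encode closely related histone-binding proteins that belong to several chromatin complexes. The 8 libraries fall into 4 groups of 2, called here the Rbbp4 knockdown, the Rbbp7 knockdown, the double knockdown and the control. Each library's group and replicate number were taken from its title. The title's word for the double group and the column name in the deposited table differ by 1 letter, and the column was matched by its gene numbers and the knockdown it names. The labels do not say that the libraries of a group came from separate embryo pools, so p-values measure only the spread between these libraries, and that spread is possibly technical.

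Per the labels' protocols, messenger RNA was captured on oligo(dT) beads, fragmented and reverse transcribed, and libraries were amplified by PCR. Trimmomatic, HISAT2, featureCounts and DESeq2, and the mouse build GRCm38, are named in the submitters' processing notes. Their versions, settings and annotation release, and whether strand was used in counting, are not given in the sources used here. The deposited values are a signal: abundance per Ensembl gene, normalized between libraries with DESeq2 by the authors per the name of the deposited table, not raw counts. Column totals ranged from 11334107 to 12011829. In each library 53.3% to 70.8% of low values lay within 0.05 of a whole multiple of the step most of them shared. Whole reads could therefore not be recovered, and no count model was fitted. Dividing the totals by that step gave a rough depth of 9200000 to 15000000 reads per library, which rests on the step being 1 read. With depth known only roughly, no counting interval is given, and genes listed at 0 in a group are reported with each library's value and no fold, except for the fitted interaction of Ndufa9. The table held 19058 genes, of which 18942 identifiers matched a symbol and 116 did not. It held 0 columns from samples outside the groups above.

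Values were analysed as log2(value + 1), so a fold change is on that scale and understates the change of genes with low values. The 12565 genes with a mean of at least 10 over the 8 libraries were tested, and 6493 were left out. A linear model with 1 mean per group was fitted to all 8 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior. The residual degrees of freedom were 4 and the prior degrees of freedom 5.18. Tests were two-sided, p-values were adjusted with the Benjamini-Hochberg method within each comparison, and genes with an adjusted p below 0.05 were called. The 7 comparisons were each knockdown against the control, the double knockdown against each single knockdown, the single knockdowns against each other, and the interaction. The interaction is the double knockdown's change minus the sum of the single knockdowns' changes. Every adjusted p for a gene comes from this limma fit with Benjamini-Hochberg adjustment. An error given after a log2 change is the standard error of the fit, and an error given after a group mean is the SD with n = 2.

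Before the data were examined, the comparisons, the test, the filter, 33 gene lists and the rule for naming genes were fixed. Of the lists, 31 had at least 5 tested members and were tested; the lists of sperm and of blood cell markers were not. The lists cover chromatin complexes, cell cycle and stress genes, embryonic lineages, genes silenced by DNA methylation or polycomb, metabolism, and cell types that could contaminate embryos. They were written from general knowledge and share some members. Lists were tested in the comparisons against the control and in the interaction with camera in limma, which compares a list with all other tested genes, at a preset correlation of 0.01 between genes. Camera was also run with a correlation estimated from these libraries, and 0 lists passed in any comparison. For the trophectoderm, junction, germline and polycomb lists the estimate was −0.021, −0.0064, −0.0046 and 0.0020. These lie below the preset, so a higher correlation does not explain why those lists no longer passed. In the other lists called at the preset, the estimate was higher, at 0.037 to 0.44. Camera with an estimated correlation also takes its p from the residual degrees of freedom, 4 here. Such a test has little power over 31 lists, so failing it does not show that a list was unchanged. The fry test in limma was added. Its directional p tests whether a list's genes move, on balance, 1 way, its mixed p whether they change in either direction, and neither compares a list with other genes. List p-values were adjusted over the 31 lists of a comparison. A member's adjusted p over all tested genes decides whether it rose or fell, and a second count adjusts its p over the list alone.

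The rule named 35 fixed genes, of which Xist had no matching identifier in the table and Zscan4c was below the filter. It also named, for each knockdown against the control, up to 10 called genes with the largest rise and up to 10 with the largest fall. These needed a mean of at least 50 in the higher group, libraries that did not overlap between groups, and a symbol that is not a predicted gene model. For other comparisons the rule took up to 5 genes each way, and for each called list against the control its 3 called members with the smallest p. Uncalled members of lists given as examples are those with the smallest p, and they were chosen after their values were seen. Coordinates come from the GENCODE annotation of GRCm38.

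The steps were tested on simulated data for the double knockdown against the control, with 12565 genes and 200 changed genes, in 10 simulations. They recovered 57.5% of 100 genes changed 2-fold and 94.6% of 100 genes changed 4-fold, with a mean of 9.2 false calls. A group without changes gave a mean of 0.8 calls. A changed list was called in 10 simulations and an unchanged list in 0. In these simulations the changed genes had a mean of at least 50, all groups had the same spread, and genes varied independently. The rates may therefore not hold for the noisier control and double knockdown, and the unchanged list does not check the preset correlation. Alternatives tried were other pseudocounts, filters and scalings, a fit of each comparison's own libraries, a block for replicate number, and leaving out each library. A robust variance prior, leaving out genes listed at 0 in any library, and library weights were added after the data were seen. To look for shared sequence, transcripts of single genes were aligned to all GENCODE transcripts with blastn 2.17.0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.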

Results

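The series measured messenger RNA in mouse late morulae whose zygotes had received siRNA against Rbbp4, Rbbp7 or both, or a non-specific siRNA as control, with 2 libraries per group. The comparisons ask how losing either protein, or both, changes gene expression before implantation, and the series title names proliferation and the histone variant H3.3. Totals of normalized abundance were 12011829 and 11712105 in the control, 11421049 and 11729642 in the Rbbp4 knockdown, 11804030 and 11860681 in the Rbbp7 knockdown, and 11653584 and 11334107 in the double knockdown. Control replicate 1 stood somewhat apart. It had 3937 genes listed at 0 against 2644 to 3237 in the other 7 libraries, and 6.21% of its signal came from mitochondrial genes against 4.26% to 5.53%. Its mean correlation with the other libraries, across genes, was 0.938, the lowest of the 8. The spread between control libraries was also the largest, with a mean within-group variance of 0.415 on the log2 scale against 0.232 in the Rbbp4, 0.236 in the Rbbp7 and 0.335 in the double knockdown. The control libraries correlated at 0.940 with each other, and control replicate 2 at 0.957 to 0.961 with the single knockdown libraries. The double knockdown libraries had 0.946 with each other, and 0.951 and 0.952 with Rbbp4 knockdown replicate 2. The Rbbp4 and Rbbp7 knockdown pairs had 0.964 and 0.965. By this measure the control and double knockdown libraries did not group by treatment, while those of each single knockdown did.

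Both targets were strongly lower in the groups that received siRNA against them. Rbbp4 (ENSMUSG00000057236, chromosome 4, 129307100 to 129335370, GRCm38) had a normalized abundance of 5005 ± 417 (SD, n = 2) in the control. It was 372 ± 42.2 in the Rbbp4 knockdown and 391 ± 60.3 in the double knockdown, 7.44% and 7.80% of the control. Its log2 changes were −3.75 ± 0.15 (adjusted p = 1.04e-05) and −3.68 ± 0.15 (adjusted p = 6.08e-06). Rbbp7 (ENSMUSG00000031353, chromosome X, 162760402 to 162779092) had 7802 ± 844 in the control, 296 ± 3.17 in the Rbbp7 knockdown and 296 ± 43.6 in the double knockdown. These are 3.79% and 3.80% of the control, with log2 changes of −4.71 ± 0.14 (adjusted p = 7.87e-07) and −4.72 ± 0.14 (adjusted p = 7.83e-07). The untargeted gene did not pass the test in either single knockdown, with −0.26 ± 0.14 for Rbbp7 in the Rbbp4 knockdown (adjusted p = 0.858) and −0.18 ± 0.15 for Rbbp4 in the Rbbp7 knockdown (adjusted p = 0.738).

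**Figure D1:**
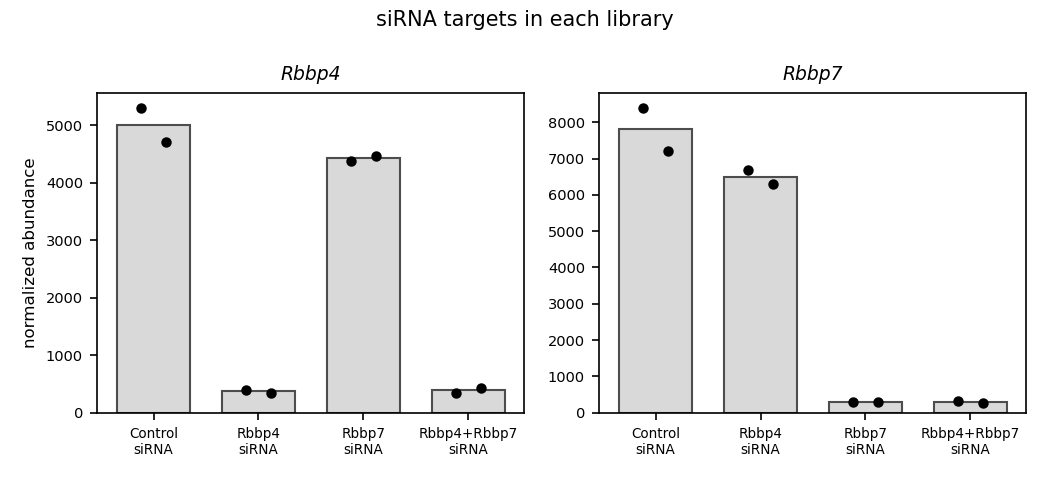
Normalized abundance of Rbbp4 (left) and Rbbp7 (right) in each group on linear axes, where bars are the mean of 2 libraries and points are the libraries. Rbbp4 was at 372 and 391 in the groups that received its siRNA against 5005 in the control, and Rbbp7 at 296 in both of its groups against 7802.

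With Rbbp4 knocked down alone, few genes passed the test. Ndufa9, a mitochondrial complex I subunit, was listed at 0 in both Rbbp4 knockdown libraries, against 276 and 468 in the control (adjusted p = 1.30e-04). Gm12613, a predicted gene, was listed at 0 in both control libraries and at 64.0 and 83.0 in the knockdown (adjusted p = 0.0404). It falls outside the naming rule, was named after its values were seen, and shares near-identical sequence with 9 other genes, so its level is uncertain. Genes of G2 and mitosis were lower as a list, with 43 of 53 members negative and a median log2 change of −0.15. Cdca3, which promotes mitotic entry, had −0.56 ± 0.13 (adjusted p = 0.604) and the proliferation marker Mki67 −0.54 ± 0.16 (adjusted p = 0.723). Cholesterol synthesis genes were higher as a list, with 21 of 24 positive and a median of 0.23. Sqle had 0.49 ± 0.12, Fdft1 0.59 ± 0.16 and Insig1 0.51 ± 0.16, and none of these 3 passed (adjusted p = 0.628, 0.723 and 0.760).

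Limma called 3 genes of 12565 in the Rbbp4 knockdown, 1 higher and 2 lower, Rbbp4 included. A p below 0.05 before adjustment was reached by 736 genes, against 628 by chance. Camera called both lists, G2 and mitosis with adjusted p = 1.44e-04 and cholesterol synthesis with adjusted p = 4.07e-04, and each had adjusted p = 0.828 with an estimated correlation. In both lists 0 members were called over all genes and 0 when adjusted over the list alone. The directional fry test passed 0 of 31 lists here, with adjusted p = 0.329 for G2 and mitosis and 0.529 for cholesterol synthesis. The cholesterol call ended without control replicate 1 (adjusted p = 0.254) and without Rbbp4 knockdown replicate 1 (adjusted p = 0.0573), within a range of 1.23e-04 to 0.828 over its alternatives. The median of that list was 0.14 without either of these libraries in turn and 0.39 without control replicate 2. Among the 31 fixed genes other than the targets 0 were called. The largest change among them was 1.48 for the endoderm factor Sox17, which had low values, and the smallest adjusted p was 0.628 for Cdkn1a, the p21 cell cycle inhibitor, with −0.86 ± 0.21. H3f3b, which encodes H3.3, had 0.24 ± 0.13 (adjusted p = 0.877). The count of called genes was 36 without control replicate 2 and 6 without Rbbp4 knockdown replicate 2. Gm12613 was called in 8 of 18 alternatives, with adjusted p between 0.0149 and 0.581, and its call ended without control replicate 1 (0.107), Rbbp4 knockdown replicate 1 (0.581) or 2 (0.350), or double knockdown replicate 1 (0.208) or 2 (0.199).

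With Rbbp7 knocked down alone, Enpep and Fabp3 fell. Enpep, a membrane aminopeptidase (ENSMUSG00000028024, chromosome 3, 129269175 to 129332720), went from 2095 ± 55.6 in the control to 681 ± 0.685, a log2 change of −1.62 ± 0.14 (adjusted p = 0.00547). Fabp3, a fatty acid binding protein on the trophectoderm list (ENSMUSG00000028773, chromosome 4, 130308595 to 130315463), went from 4606 ± 60.4 to 1756 ± 322, a log2 change of −1.40 ± 0.15 (adjusted p = 0.0176). Trophectoderm genes, those of the outer lineage that forms the placenta, were lower as a list, with 26 of 32 negative and a median of −0.45. The keratins Krt18 and Krt8 had −1.51 ± 0.19 (adjusted p = 0.0616) and −1.21 ± 0.19 (adjusted p = 0.122), and the sodium pump subunit Atp1b1 had −0.99 ± 0.14 (adjusted p = 0.0916). The lineage transcription factors Gata3 and Cdx2 had −0.53 ± 0.13 (adjusted p = 0.252) and −0.32 ± 0.21 (adjusted p = 0.659), and neither passed.

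The list of compaction, junction and cavitation genes had a median of −0.12 over 34 members, 23 of them negative. Its members with the smallest p after Atp1b1 were the desmosome and junction genes Dsp (−0.65 ± 0.18), Jup (−0.59 ± 0.17) and Epcam (−0.62 ± 0.18). Small positive changes ran through the protein synthesis lists, with a median of 0.14 and 69 of 74 positive for cytosolic ribosomal proteins and 0.16 with 35 of 42 positive for ribosome biogenesis. Rpl34 had 0.35 ± 0.12 and the RNA polymerase I and III subunit Polr1c 0.67 ± 0.22. Cholesterol synthesis genes had a median of 0.20 with 17 of 24 positive, and Fdft1 had 0.68 ± 0.16. In these 4 lists 0 members were called over all genes, and 1, Atp1b1 in the junction list, when adjusted over the list alone. Nanog, a pluripotency factor, had 0.56 ± 0.11 (adjusted p = 0.168) and Hdac1 0.56 ± 0.11 (adjusted p = 0.163). H3f3b had −0.10 ± 0.13 (adjusted p = 0.846) and Sox17 1.74 ± 0.73 (adjusted p = 0.504). The fixed genes other than the targets included 0 called of 31.

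Limma called 3 genes in the Rbbp7 knockdown, 0 higher and 3 lower, Rbbp7 included, and 1200 genes had an unadjusted p below 0.05. Camera called the trophectoderm list with adjusted p = 1.38e-07 and with adjusted p = 0.0793 with an estimated correlation. In that list 1 member fell over all genes and 11 fell when adjusted over the list alone. The junction list had adjusted p = 0.0387 (adjusted p = 0.533 with an estimated correlation) and ribosomal proteins adjusted p = 7.19e-05 (adjusted p = 0.786 with an estimated correlation). Ribosome biogenesis had adjusted p = 9.97e-04 (adjusted p = 0.786 with an estimated correlation) and cholesterol synthesis adjusted p = 0.0233 (adjusted p = 0.812 with an estimated correlation). By the directional fry test the trophectoderm list (adjusted p = 0.00165) and the junction list (adjusted p = 0.0453) moved 1 way, and ribosomal proteins (0.339), ribosome biogenesis (0.314) and cholesterol synthesis (0.578) did not pass. Leaving out a single library changed the count of called genes from 3 to between 1, without control replicate 1 or Rbbp7 knockdown replicate 2, and 38, without control replicate 2, with 10 without Rbbp7 knockdown replicate 1 and 2 without either Rbbp4 knockdown library. Fabp3 was lost without control replicate 1 (adjusted p = 0.101), Rbbp4 knockdown replicate 1 (0.0547) or 2 (0.0631), or Rbbp7 knockdown replicate 2 (0.143), within a range of 0.00496 to 0.152. Enpep was lost without control replicate 1 (0.0533) or Rbbp7 knockdown replicate 2 (0.121), within a range of 0.00142 to 0.121. Among lists, ribosomal proteins were lost without control replicate 1 (0.197), ribosome biogenesis without control replicate 2 (0.0592), and cholesterol synthesis without control replicate 1 (0.447) or Rbbp7 knockdown replicate 2 (0.243). The junction list was lost without control replicate 2 (0.303), Rbbp4 knockdown replicate 1 (0.0686) or 2 (0.0680), Rbbp7 knockdown replicate 1 (0.0833) or 2 (0.135), or double knockdown replicate 1 (0.0519) or 2 (0.0534). The medians themselves moved, to 0.055 for cholesterol synthesis and 0.065 for ribosomal proteins without control replicate 1, and to 0.25 for ribosomal proteins without control replicate 2.

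With both genes knocked down, many more genes passed. H3f3b, which encodes the histone variant H3.3 (ENSMUSG00000016559, chromosome 11, 116021912 to 116027962), rose from 6716 ± 224 to 12828 ± 277, a log2 change of 0.93 ± 0.13 (adjusted p = 0.0208), while the other H3.3 gene, H3f3a, had 0.13 ± 0.14 (adjusted p = 0.659). H3f3b shares near-identical sequence with 3 annotated genes, of which 1 was in the table. Plet1, a surface protein known from trophoblast progenitors (ENSMUSG00000032068, chromosome 9, 50494525 to 50505482), fell from 1095 ± 44.7 to 309 ± 44.0, a log2 change of −1.83 ± 0.20 (adjusted p = 0.0114). Elovl3, a fatty acid elongase (ENSMUSG00000038754, chromosome 19, 46131897 to 46135694), had the largest rise of the genes that the rule named, from 4.91 ± 1.56 to 178 ± 25.8, a log2 change of 4.94 ± 0.57 (adjusted p = 0.0114). The developmental transcription factor Sox9 rose by 2.19 ± 0.30 (adjusted p = 0.0178).

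Genes of G2 and mitosis were lower as a list in the double knockdown, with 46 of 53 negative and a median log2 change of −0.28. Cdca3 fell by 0.94 ± 0.13 and the condensin subunit Ncapd2 by 0.87 ± 0.15, while Mki67 (−0.81 ± 0.16) and the spindle midzone gene Prc1 (−0.52 ± 0.12) did not pass. In that list 2 members fell over all genes and 12 fell when adjusted over the list alone. Targets of the tumour suppressor p53 were higher as a list, with 24 of 34 positive and a median of 0.32. Pmaip1, a pro-apoptotic gene, rose by 0.96 ± 0.14, Ddit4l, an inhibitor of mTOR signalling, by 1.18 ± 0.18, and Zmat3, an RNA-binding protein, by 0.79 ± 0.14. Plk2 (0.93 ± 0.18), Phlda3 (0.75 ± 0.15) and Mdm2 (0.62 ± 0.13), which limits p53, did not pass, with adjusted p = 0.0511, 0.0530 and 0.0646. Over all genes 3 members rose, and adjusted over the list alone 12 rose and 1, Tigar (−0.56 ± 0.13), fell. Cdkn1a, also on this list, did not rise, at 3723 ± 1186 against 4349 ± 92.8 in the control, and did not pass.

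Trophectoderm genes were lower as a list, with 23 of 32 negative and a median of −0.22. Id2, an inhibitor of basic helix-loop-helix factors, fell by 1.62 ± 0.21, Atp1b1 by 1.13 ± 0.14, Fabp3 by 0.97 ± 0.15 and Krt18 by 1.08 ± 0.19, while the keratin Krt19 rose by 3.43 ± 0.57. Over all genes 4 members fell and 1 rose, and adjusted over the list alone 9 fell and 1 rose. Germline genes normally repressed by DNA methylation were higher, with 21 of 26 positive and a median of 0.47. Sycp1, a synaptonemal complex protein, rose by 1.43 ± 0.27, and Tuba3a had 1.77 ± 0.39 (adjusted p = 0.0691). Over all genes 1 member rose, and 2 rose when adjusted over the list alone. Developmental regulators listed as marked by polycomb were higher, with 24 of 30 tested members positive and a median of 0.50, or 0.24 under quantile normalization. The list named 89 genes, of which 81 were in the table and most fell below the filter. No polycomb mark was measured in these embryos. Sox9 was the 1 member that rose, by either adjustment, and the growth factor gene Bmp2 had 2.73 ± 0.74 (adjusted p = 0.113). Cytosolic ribosomal proteins had a median of 0.11 with 60 of 74 positive, and Rpl9 had 0.32 ± 0.11. In that list 0 members were called by either adjustment.

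**Figure D2:**
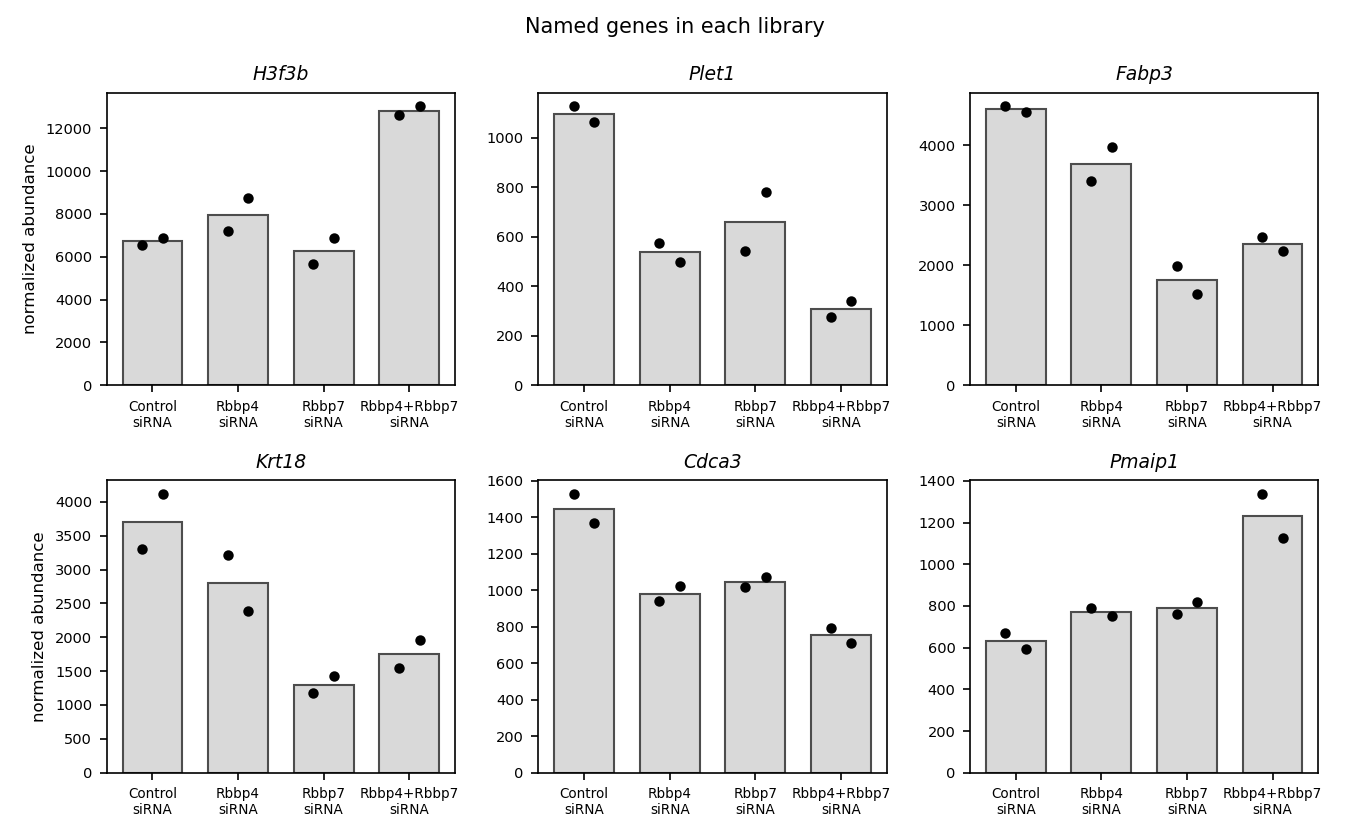
Normalized abundance of 6 named genes on linear axes, where bars are the mean of 2 libraries and points are the libraries. H3f3b stood at 12828 in the double knockdown against 6716 in the control, and Plet1 at 309 against 1095.

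Other genes with large rises were Krt19, the adenylate cyclase Adcy5 (3.07 ± 0.42), Cdhr2 (2.74 ± 0.47), the bicarbonate transporter Slc4a8 (2.44 ± 0.43), the lectin Mgl2 (2.43 ± 0.37), Pnma2 (2.36 ± 0.45), Bbs7 (2.29 ± 0.33) and Synm (2.29 ± 0.41). Large falls were seen for Pcbp4 (−2.81 ± 0.39), Katnal1 (−2.71 ± 0.46), Nckipsd (−2.47 ± 0.45), Spata13 (−2.38 ± 0.45), Tcf4 (−2.15 ± 0.40), the interferon regulatory factor Irf3 (−1.98 ± 0.36), Cpxm1 (−1.94 ± 0.25) and Vtcn1 (−1.93 ± 0.31). Pomgnt2 was listed at 0 in both double knockdown libraries, against 44.5 and 64.1 in the control. Enpep, named here after its values were seen, also fell, by 0.85 ± 0.14. Gm12613, uncertain for its shared sequence, was listed at 151 and 130 against 0 and 0.

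Of the 31 fixed genes other than the targets, H3f3b was the 1 that passed in the double knockdown. Nanog had −0.55 ± 0.11 (adjusted p = 0.0573), Gata3 −0.53 ± 0.13 (adjusted p = 0.0943) and Cdx2 −0.80 ± 0.21 (adjusted p = 0.101). Changes below −0.25 that did not pass were −0.60 for Krt8, −0.27 for Tead4, −1.32 for Sox2, −0.32 for Cdk1, −0.26 for Cdkn1a, −0.36 for Chd4 and −0.42 for Ezh2. Changes above 0.25 that did not pass were 2.33 for Sox17, 0.89 for Ccnd1, 0.62 for Mdm2, 0.28 for Hira, 0.38 for Daxx and 0.48 for Hdac2. Eomes (−0.17), Klf4 (0.10), Gata6 (−0.055), Trp53 (0.21), Asf1a (0.025), Chaf1a (−0.053), Mta1 (0.16), Cdh1 (−0.18) and Yap1 (0.16) also did not pass. Pou5f1 (0.013), Hdac1 (−0.0023), Eed (−0.020) and Dnmt1 (−0.035) lay so near 0 that their sign flipped under quantile normalization, and for Pou5f1 also under TMM scaling.

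Limma called 144 genes in the double knockdown, 81 higher and 63 lower, of which 105 changed at least 2-fold, 68 higher and 37 lower. An unadjusted p below 0.05 was reached by 2176 genes. The count depended on the fit: with the 4 control and double knockdown libraries alone, 2 genes passed, and with weights that allow for the noisier groups, 38 passed. Leaving out a library gave 27 without double knockdown replicate 1, 33 without its replicate 2, 30 and 43 without Rbbp4 knockdown replicates 2 and 1, 47 without control replicate 1, 70 and 71 without Rbbp7 knockdown replicates 2 and 1, and 99 without control replicate 2. Of the 46 called genes named here or among the other observations, between 6, without double knockdown replicate 1, and 29, without Rbbp7 knockdown replicate 1, were still called when a library was left out. With only the control and double knockdown libraries 0 of the 46 were still called, and with library weights 19. H3f3b was lost in 6 of 19 alternatives, with adjusted p between 0.0109 and 0.111 and log2 changes between 0.90 and 0.97. These were the fit of the comparison's libraries (0.111), library weights (0.0669), and the fits without control replicate 1 (0.0837) or 2 (0.0540) or double knockdown replicate 1 (0.0754) or 2 (0.0697). Camera called G2 and mitosis (adjusted p = 1.04e-07; adjusted p = 0.188 with an estimated correlation), germline genes (0.00171; adjusted p = 0.188 with an estimated correlation) and p53 targets (0.00527; adjusted p = 0.337 with an estimated correlation). It also called polycomb-marked regulators (adjusted p = 0.00631; adjusted p = 0.188 with an estimated correlation), trophectoderm (0.0127; adjusted p = 0.188 with an estimated correlation) and ribosomal proteins (0.0314; adjusted p = 0.799 with an estimated correlation). By the directional fry test 6 lists passed, each with adjusted p = 0.0187. They were 5 of these lists and the MuvB and MYB genes, which camera did not call, while ribosomal proteins did not pass (adjusted p = 0.291). The p53 call ended without control replicate 2 (adjusted p = 0.0646), and the polycomb call with a filter at a mean of 50 (0.0507) and under quantile normalization (0.0982). The ribosomal call ended in 10 of 18 alternatives, among them TMM scaling (0.0540) and the fits without control replicate 1 (0.763), double knockdown replicate 2 (0.294), Rbbp4 knockdown replicate 1 (0.0525) or 2 (0.0523), or Rbbp7 knockdown replicate 1 (0.0603) or 2 (0.0603). The ribosomal median was 0.038 without control replicate 1, 0.20 without its replicate 2 and 0.071 without double knockdown replicate 2, and the polycomb median was 0.24 under quantile normalization.

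**Figure D3:**
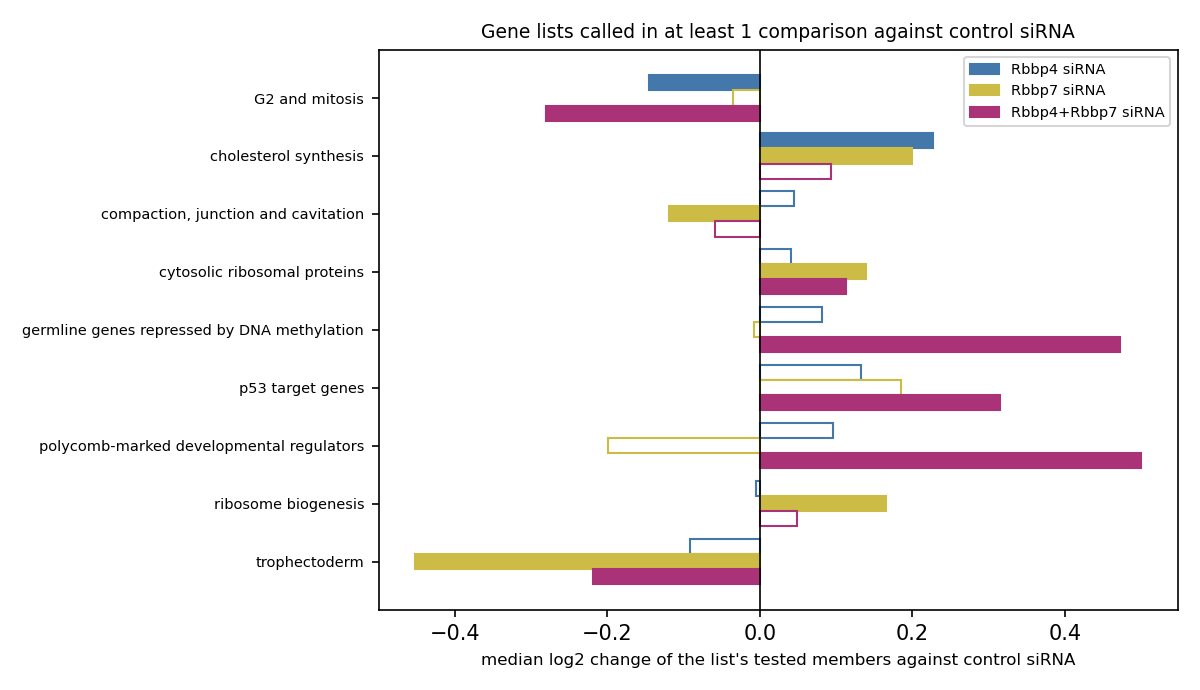
Median log2 change against the control of the tested members of each gene list called in at least 1 knockdown, where filled bars passed the camera test at the preset correlation and open bars did not. G2 and mitosis stood at −0.15 in the Rbbp4 knockdown and −0.28 in the double knockdown, and trophectoderm at −0.45 in the Rbbp7 knockdown and −0.22 in the double knockdown.

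The double knockdown was next compared with each single knockdown. Against the Rbbp7 knockdown, Nanog was lower, at 4442 ± 354 against 9625 ± 752, a log2 change of −1.12 ± 0.11 (adjusted p = 0.00916), and H3f3b was higher by 1.04 ± 0.13 (adjusted p = 0.0177). The genes with the largest rises were the transcription factor Sall3 (5.22 ± 0.65), Elovl3 (4.40 ± 0.57), Wipi1 (2.75 ± 0.39), Avil (2.59 ± 0.36) and the galectin Lgals9 (2.59 ± 0.30). The largest falls were in Slc41a1 (−1.71 ± 0.28), Ankrd50 (−1.65 ± 0.24), Dok1 (−1.45 ± 0.23) and Nr4a1 (−1.33 ± 0.20), and Btbd6 was listed at 0 in both double knockdown libraries against 56.2 and 81.3. Against the Rbbp4 knockdown, Rbbp7 fell by 4.46 and Ndufa9 was at 476 and 323 against 0 and 0. Limma called 45 genes against the Rbbp7 knockdown, 30 higher and 15 lower, Rbbp4 among the latter, with 1879 at an unadjusted p below 0.05. It called 2 genes against the Rbbp4 knockdown, Rbbp7 and Ndufa9, with 1203 at an unadjusted p below 0.05. H3f3b, at 7956 ± 1092 in the Rbbp4 knockdown, and Nanog did not pass there. Neither was therefore told apart between the double and the Rbbp4 knockdown. With only the 4 libraries of the comparison, 1 gene passed against the Rbbp7 knockdown. Leaving out single libraries gave 5 without Rbbp7 knockdown replicate 2, 12 without its replicate 1, 15 and 28 without double knockdown replicates 1 and 2, 23 and 21 without Rbbp4 knockdown replicates 1 and 2, and 41 and 42 without control replicates 2 and 1. Of the 12 genes named for that comparison, targets aside, 0 were still called without Rbbp7 knockdown replicate 2 and 10 without either control library. Against the Rbbp4 knockdown the count was 4 without control replicate 1, 4 and 9 without Rbbp4 knockdown replicates 1 and 2, and 7 and 13 without double knockdown replicates 1 and 2.

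The single knockdowns differed from each other in 10 genes, 8 higher and 2 lower in the Rbbp4 knockdown. Apart from the targets, Enpep was higher by 1.82 ± 0.14 (adjusted p = 9.91e-04), Dcbld2 by 1.59 ± 0.15, the endocytic receptor Cubn by 1.49 ± 0.15, the lysosomal sialidase Neu1 by 1.46 ± 0.18, Tmem64 by 1.41 ± 0.18 and Fabp3 by 1.08 in the Rbbp4 knockdown. Gm12613, at 64.0 and 83.0 against 0 and 0, was also higher, and Ndufa9 lower, at 0 and 0 against 459 and 172. An unadjusted p below 0.05 was reached by 1168 genes. The count rose to 65 with library weights and to 18 with only the 4 libraries of the comparison, and it was 6 without Rbbp7 knockdown replicate 2 and 15 without its replicate 1. Of the 8 genes named, targets aside, 2 were still called without Rbbp4 knockdown replicate 2, 3 without its replicate 1, 4 without Rbbp7 knockdown replicate 2, and 6 without any other single library.

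With 3 genes called in each single knockdown, at most 3 could be shared. The Rbbp4 and double knockdowns shared 2 in the same direction, Rbbp4 and Gm12613, the Rbbp7 and double knockdowns 3, Rbbp7, Enpep and Fabp3, and the single knockdowns 0. Sharing of a target is set by the design. Without the targets the counts were 1, 2 and 0, against 0.0113, 0.00971 and 1.59e-04 for independent lists and means of 0.06, 0.06 and 0.1 in 50 simulations of unchanged groups with shared controls. With the targets, the counts were 30, 31 and 26 without control replicate 2, and at most 2, 2 and 0 without other single libraries. At an unadjusted p below 0.05 and without the targets, 405 genes had changes of the same sign in the Rbbp4 and double knockdowns, against 63.6 for independent lists and 137 in the simulations. The numbers were 449 against 103 and 135 for the Rbbp7 and double knockdowns, and 196 against 35.0 and 138 for the single knockdowns. The simulated groups held no changes and were not matched to the number of genes passing at either threshold. Independent lists ignore the shared controls. Neither is therefore a baseline for these shared counts, and no conclusion is drawn from them. Across genes, log2 changes of the Rbbp4 and double knockdowns had r = 0.57 (simulated 0.50) and a covariance of 0.231 (simulated 0.111). For the Rbbp7 and double knockdowns r was 0.49 (simulated 0.50) and the covariance 0.211 (simulated 0.111), and for the single knockdowns 0.52 (simulated 0.50) and 0.178 (simulated 0.111). Genes are not independent replicates. The spread between the control libraries alone gives a covariance of 0.208. The covariances differed from it by 0.023 for the Rbbp4 and double, 0.0036 for the Rbbp7 and double, and −0.030 for the single knockdowns. The simulations gave a gene the same spread in every group, so they lacked the larger spread of the control. The excess over the simulations therefore does not show a shared response. The 2 control libraries were not split between comparisons, which would have left 1 for each.

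The interaction asks whether the double knockdown differed from the sum of the single ones. Limma called 1 gene, Ndufa9, which was listed at 0 in the Rbbp4 knockdown alone (adjusted p = 0.00344), and 815 genes had an unadjusted p below 0.05 against 628 by chance. H3f3b had an interaction of 0.80 ± 0.19 (adjusted p = 0.593) and Nanog −1.07 ± 0.16 (adjusted p = 0.369), and neither passed. Over the 143 genes called in any knockdown against the control, targets aside, the double change and the sum of single changes had the same sign in 141, and both single changes had that sign in 116. In 50 simulations of unchanged groups with shared controls, the 143 genes with the smallest p in the double gave means of 136 and 121, with highest values of 140 and 130, so shared controls alone give counts near these. The median size was 1.32 for the double change and 0.99 for the sum, and the slope of the first on the second was 0.80, with 0.39 to 0.72 when single libraries were left out and 0.71 in the simulations. Most of these genes were chosen because their double change was large, which favours the double change, so the comparison is descriptive. Lists called in the interaction were genes of the 2-cell stage (median 1.55), cholesterol synthesis (−0.40) and germline genes (0.35), with adjusted p = 0.00283, 0.00283 and 0.0424. With an estimated correlation these had adjusted p = 0.745, 0.745 and 0.488, and the directional fry test passed 0 of 31 lists. The 2-cell list had 19 of 21 positive interactions, with medians against the control of −0.85 in the Rbbp4, −0.93 in the Rbbp7 and 0.40 in the double knockdown, none of them called (adjusted p = 0.417, 0.189 and 0.343), and 0 members were called over all genes and 1, Gm5662 (2.33 ± 0.52), when adjusted over the list alone. In the cholesterol list 22 of 24 were negative and in the germline list 19 of 26 positive, and in both 0 members were called by either adjustment. The 2-cell call ended without control replicate 2 (adjusted p = 0.153), Rbbp7 knockdown replicate 2 (0.0959) or double knockdown replicate 1 (0.165), and the cholesterol call without control replicate 1 (0.0594) or double knockdown replicate 1 (0.165). The germline call ended without control replicate 1 (0.183), Rbbp7 knockdown replicate 1 (0.0516) or double knockdown replicate 1 (0.194), and under quantile normalization (0.0839). The 2-cell median was 2.89 without control replicate 1, 0.73 without its replicate 2 and 0.58 with a filter at a mean of 50. The cholesterol median was −0.22 without control replicate 1 and −0.25 without double knockdown replicate 1, and the germline median 0.15, 0.21 and 0.11 without Rbbp4 knockdown replicate 2, Rbbp7 knockdown replicate 2 and double knockdown replicate 1. Of the lists called in the double knockdown, these had interactions that did not pass, with medians of 0.14 for trophectoderm (adjusted p = 0.0501), 0.26 for polycomb-marked regulators (0.0501), −0.11 for G2 and mitosis (0.12), −0.08 for ribosomal proteins (0.12) and 0.03 for p53 targets (0.420). The count of genes was 21 without control replicate 2, 6 without Rbbp7 knockdown replicate 1, 2 and 3 without Rbbp4 knockdown replicates 1 and 2, and 4 and 3 without double knockdown replicates 1 and 2.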

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

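The tests of Gm12613's shared sequence, of library scaling for H3f3b, and of the 2-cell list were chosen only after the result was seen. The interaction test passed for Ndufa9 and, by camera at the preset correlation, for 3 gene lists. Ndufa9 had a fitted interaction of 8.97 log2, which is no bound and ranged from 6.66 to 9.97 over the alternatives, because the gene was listed at 0 in the Rbbp4 knockdown. The median interaction was 1.55 log2 for genes of the 2-cell stage, 0.35 for germline genes repressed by DNA methylation and −0.40 for cholesterol synthesis genes. With an estimated correlation these lists had adjusted p = 0.745, 0.488 and 0.745, and the directional fry test passed 0 lists.

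Ndufa9 was listed at 0 and 0 in the Rbbp4 knockdown, Pomgnt2 and Btbd6 at 0 and 0 in the double knockdown, and Gm12613 at 0 and 0 in the control. No gene shared at least 100 bases at 97% identity with Ndufa9, Pomgnt2 or Btbd6, so 0% of their change moved to such genes, which argues against reads assigned to a near-identical gene. Values missing at random may account for such pairs, but the test cannot decide. Genes at 0 in both libraries and at least 50 in the other 6 had a mean number of 0.25 over same-group pairs. The mean over other pairs was 0.417, which meets the bound for that explanation. The totals were 1, Ndufa9, over 4 same-group pairs and 10 over 24 other pairs, too few to tell. Pomgnt2, Btbd6 and Gm12613 did not meet the criterion, so it says nothing about them. For Gm12613 in the double knockdown, shared sequence and a real change cannot be told apart: its relative Gm12614 went from 106 and 94.1 in the control to 0 and 0, a loss of 71.2% of Gm12613's gain. Its 9 relatives together moved the same way (−38.8%), which under the bound first written would have excluded the explanation, but abundant relatives such as Gm12616, at 1110 and 1144 in the control and 1307 and 1080 in the double knockdown, swamp that sum.

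H3f3b stood at 12828 ± 277 in the double knockdown against 6716 ± 224 in the control. The lower of its log2 changes under TMM and quantile scaling was 0.92. TMM factors of the normalized libraries ran from 0.989 to 1.013, so that rescaling could hardly move any gene. The test therefore argues only against a scaling difference that these methods detect. A scaling error common to them and DESeq2 was not tested. Reads assigned from genes of near-identical sequence cannot be told apart from a real change. Of 3 such genes only 1, Gm6485, was in the table. At 0 and 0 in the control Gm6485 had no signal to lose, so it was not the source of the gain. Its share of the gain (−0.00958%) meets the bound first written, but the genes without a value stay untested. A biological response to losing both proteins stays open as a hypothesis, and the interaction of 0.80 ± 0.19 (adjusted p = 0.593) did not pass.

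The interaction of the 2-cell list mean was 1.505, from means of 6.32 in the control, 5.59 in each single knockdown and 6.36 in the double knockdown, so the single knockdowns lay lower and the double near the control. The control libraries differed from each other by 1.80 in that mean, at 5.42 and 7.22, so members that vary together between libraries of 1 group may account for it. The call held in 5 of the 8 fits that left out a library, and ended without control replicate 2, Rbbp7 knockdown replicate 2 or double knockdown replicate 1. A biological difference between losing 1 protein and losing both was not separated from these.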

How the results depend on the processing

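The robust variance prior, leaving out genes listed at 0 in any library, library weights and every alternative for the slope of double on summed changes were chosen after seeing the data. The edgeR and DESeq2 alternatives were not run, because whole reads could not be recovered. Both targets kept their direction and their side of the threshold in all 190 tests of them. Other named genes kept both in 1339 tests under other settings, while 126 calls were lost, 23 were gained and 5 signs reversed, and in 754 tests with a library left out, while 329 were lost, 2 gained and 18 reversed. These settings include the fit of a comparison's own 4 libraries, which kept 0 of the 46 genes named and called in the double knockdown. Tests that kept both include genes that were uncalled before and stayed uncalled. Their number therefore does not measure how well calls held. Calls of lists held in 132 and were lost in 25 tests under other settings, and held in 100 and were lost in 28 with a library left out. Leaving out a library leaves an arm with 1 library, which is assumed to vary like the other groups. Depth is known only roughly, so no upper limit is given for genes listed at 0.

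Without genes listed at 0 in any library, calls numbered 1 for the Rbbp4 knockdown (3 before), 8 for the Rbbp7 knockdown (3), 217 for the double knockdown (144), 1 for double against Rbbp4 knockdown (2), 109 for double against Rbbp7 knockdown (45), 21 between the single knockdowns (10) and 0 for the interaction (1), and 8 lists in the interaction (3). The genes at 0 left the test there, Ndufa9 included. A filter at a mean of 50, which tests fewer genes, gave 6 for the Rbbp7 knockdown and 78 for double against Rbbp7 knockdown. A pseudocount of 5 gave 5 for the Rbbp7 knockdown, as did the robust prior. With only the libraries of the comparison, 2 were called for the double knockdown, 1 for double against Rbbp7 knockdown and 18 between the single knockdowns. Library weights gave 38 and 65 for the double knockdown and between the single knockdowns, and the 38 were all among the 144. A replicate block gave 113 for the double knockdown, 102 of them shared, but replicate numbers do not pair the libraries, with correlations of −0.022 to 0.051.

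With an estimated correlation 0 lists were called for the Rbbp4 knockdown (2 before), the Rbbp7 knockdown (5), the double knockdown (6) and the interaction (3). With no filter 3 lists were called for the Rbbp7 knockdown. In the interaction 7 were called with a pseudocount of 0.5, 8 with 5, 6 with the filter at 50 and 8 with TMM scaling. Calls shared by the Rbbp4 and double knockdowns were 1 with the filter at 50 and 1 with quantile normalization (2 before), and those shared by the Rbbp7 and double knockdowns 1 at a change of at least 2-fold (3 before). The slope of double on summed changes was 1.045 without genes listed at 0 and 0.686 with library weights (0.804 before). In the double knockdown Pou5f1 reversed to −0.0023 with TMM scaling and −0.0062 with quantile normalization, and quantile normalization reversed Hdac1 to 0.045, Eed to 0.020 and Dnmt1 to 0.016. Where no reason is given, the cause was not tested.

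Leaving out 1 library gave 2 to 36 calls for the Rbbp4 knockdown, 1 to 38 for the Rbbp7 knockdown and 27 to 99 for the double knockdown. It gave 2 to 13 for double against Rbbp4 knockdown, 5 to 42 for double against Rbbp7 knockdown, 6 to 15 between the single knockdowns and 1 to 21 for the interaction. The highest counts of both single knockdowns, the double knockdown and the interaction came without control replicate 2. Lists called ranged from 1 to 4, 3 to 6 and 2 to 7 for the Rbbp4 knockdown, the Rbbp7 knockdown and the interaction. Shared calls ranged from 1 to 30 for the Rbbp4 and double, 1 to 31 for the Rbbp7 and double, and 0 to 26 for the Rbbp4 and Rbbp7 knockdowns, and the slope from 0.391 to 0.723. Uncalled genes whose sign reversed had these ranges: in the Rbbp7 knockdown Cdx2 −0.67 to 0.027 and H3f3b −0.24 to 0.038; in the double knockdown H3f3a −0.045 to 0.31, Cdkn1a −0.59 to 0.069, Pou5f1 −0.14 to 0.16, Gata6 −0.13 to 0.022, Eomes −0.54 to 0.21, Asf1a −0.29 to 0.34, Chaf1a −0.12 to 0.013, Hdac1 −0.050 to 0.045, Eed −0.17 to 0.13, Mta1 −0.082 to 0.40 and Dnmt1 −0.077 to 0.0067.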

Other observations

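The genes named in this part were chosen after their values were seen, and no further tests were run for it. Camera did not call the lists of the complexes that contain Rbbp4 or Rbbp7 in the double knockdown. The median log2 change was −0.06 for the NuRD complex (12 members, adjusted p = 0.581) and −0.11 for the SIN3 complex (13 members, adjusted p = 0.687), with 0 members called in either over all genes, and 0 in the first and 1 up and 1 down in the second when adjusted over the list alone. It was −0.07 for polycomb repressive complex 2 (adjusted p = 0.288), where the accessory subunit Mtf2 fell by 0.78 ± 0.11. MuvB and MYB genes had −0.25 with 0 of 6 positive (adjusted p = 0.0591), 0 members called over all genes and 1 that fell when adjusted over the list alone, and they moved 1 way by the directional fry test (adjusted p = 0.0187). By the mixed fry test, which asks for change in either direction, polycomb repressive complex 2 (adjusted p = 7.59e-04), SIN3 (7.73e-04) and MuvB and MYB (0.00260) passed and NuRD (0.294) did not, but 24 of the 31 lists passed that test, so it does not single these out. The list of H3 chaperones and H3.3 genes had 0.03 (adjusted p = 0.764), where H3f3b alone rose. Machinery of DNA and H3K9 methylation had −0.21 with 18 of 24 negative (adjusted p = 0.0591). There the corepressor Trim28 fell by 0.62 ± 0.11 and the 5-methylcytosine dioxygenase Tet1 rose by 0.75 ± 0.13, and adjusted over the list alone 5 members fell and 1 rose. Hippo pathway genes had −0.15 with 18 of 25 negative (adjusted p = 0.0833), where the kinase cofactor Mob1a fell by 0.93 ± 0.13.

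Other lists that were not called in the double knockdown had medians of −0.03 for replication-dependent histone genes (adjusted p = 0.343), −0.07 for DNA replication (0.393), −0.10 for homologous recombination and checkpoint genes (0.393) and 0.04 for apoptosis regulators (0.687). Of 67 replication-dependent histone genes in the table, 12 passed the filter, and RNA was captured on oligo(dT) beads. The histone list therefore says little about that class. Lineage and stage lists had −0.04 for epiblast and pluripotency (adjusted p = 0.732), 0.13 for primitive endoderm (0.251), 0.40 for 2-cell genes (0.343), 0.15 for maternal transcripts (0.732), 0.05 for imprinted genes (0.541) and −0.06 for compaction, junction and cavitation (0.362). Metabolic and stress lists had −0.12 for mitochondrially encoded genes (adjusted p = 0.393), −0.0015 for oxidative phosphorylation (0.732), −0.0083 for glycolysis (0.732), 0.09 for cholesterol synthesis (0.343), 0.05 for ribosome biogenesis (0.898), 0.0038 for the integrated stress response (0.935) and 0.23 for the interferon response (0.650). Members of these lists that were called over all genes were Pmaip1 (apoptosis), Tet1 (pluripotency), Ddit4l and Tdpoz2 (2-cell; Tdpoz2 rose by 0.96 ± 0.19), Cd81 (imprinted; rose by 1.46 ± 0.20), Atp1b1 (compaction) and lactate dehydrogenase Ldha (glycolysis; rose by 1.61 ± 0.25). Adjusted over the list alone, 4 rose and 1 fell among 2-cell genes, 3 rose and 1 fell among imprinted genes, 1 rose and 1 fell among pluripotency genes, and 2 fell among compaction genes. By the same adjustment 3 rose among the 12 tested replication-dependent histones, 3 in cholesterol synthesis, and 1 each in apoptosis, primitive endoderm, glycolysis and the stress response. Markers of cumulus and granulosa cells, which surround the oocyte, had a median of 0.29 and a mean of 1.02 over 6 members (adjusted p = 0.687), and passed the mixed fry test (adjusted p = 4.70e-04) but not the directional one (0.976). Nr4a1 fell by 1.25 ± 0.20, and adjusted over the list alone Foxl2 (2.14 ± 0.51) and Vcan also passed, upward. Vcan was listed at 0 and 0 in the control and at 113 and 6.59 in the double knockdown.

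Genes outside the lists that rose in the double knockdown included the protease Plau (2.05 ± 0.23) and the phosphatase Dusp1 (1.79 ± 0.27). Among those that fell were the RNA-binding protein Hnrnpc (−1.37 ± 0.17) and the MYC partner Max (−0.80 ± 0.12). Btbd6 was listed at 0 in both double knockdown libraries against 15.2 and 71.1 in the control (adjusted p = 0.0237).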
